A study of Mus musculus with 2 samples.

How the data were processed

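Expression was measured in feeder-free mouse embryonic stem (ES) cells, grown with serum and leukaemia inhibitory factor. The cells carried a retrovirus that expressed either a control short-hairpin RNA or one directed at the histone variant H2A.B, and per the labels' protocols they were kept under G418 selection for 2 to 4 weeks. From each culture 2 µg of total RNA was reverse-transcribed from an oligo(dT) primer with a T7 promoter, labelled with biotin and hybridised to an Affymetrix expression array. There was 1 array per group. The knockdown sample's title numbers it 1, and the labels do not state what that number stands for.

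The values were made with RMA, per the submitters' processing notes, with no version stated. RMA corrects the background, normalises the quantiles between arrays and summarises the probes of each probe set. The deposited table does not state its scale; the control column runs from 0.801 to 14.5, as log2 intensities from RMA do, and was used as such. In the knockdown column as deposited, a search for step series and for values above 20 marked 618 values as not log2 intensities. Of those, 616 form a series that rises in steps of 1 from 4.11 to 619 and lies among ordinary values between rows 2054 and 4710, and the other 2 are 42 and 4.88e+14. These 618 values were left out. At 174 of the other positions both arrays had the same value, and these were not left out on that account. The usable values had a median of 5.63 on the control array and 5.59 on the knockdown array. An array gives no count of reads, and the number of arrays limits the precision.

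In the control column, 1455 values were identical, to the last deposited digit, to a value up to 20 rows above in one of the columns. Of these, 1115 matched a control value and 340 a knockdown value. All of them lay between rows 18185 and 33642, and 0 lay elsewhere. They were left out in the main setting. Knockdown values were not searched for such repeats. The rows before, between and after these limits are called the first, middle and last section, with 18184, 15458 and 11476 probe sets.

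Probe sets were named from the platform annotation supplied with the table. Of 45118 probe sets, 28898 named 1 gene, 551 named several and 15669 named none; 81 of the table's probe sets are Affymetrix controls. Gene identifiers of 28689 single-gene probe sets were found in a gene table of the GRCm38.p6 assembly, which was used for symbols and chromosomes. Only probe sets naming 1 gene entered the gene results.

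Each gene was given the value of its probe set with the highest mean over both arrays, which left 16563 genes. The 8282 genes with a mean at or above the median over genes, 6.73 on the log2 scale, passed the expression filter. No centring was added. With 1 array per group there is no test, and the results give log2 differences, knockdown minus control, with a fixed rule of size, a difference of at least 2-fold. The only spread available is technical and lies within the 2 arrays: the SD of the difference among probe sets of one gene had a median of 0.05 over 2556 genes.

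In advance, 37 gene lists were fixed. The median difference of a list was placed among 10000 random lists of the same size drawn from genes matched on mean expression in 20 bins, and a percentile below 2.5 or above 97.5 is called outside the central range. Such percentiles describe these 2 arrays and are not p-values. The genes named are the 15 with the largest difference in each direction, up to 4 members of each list with the largest absolute difference, all members of the imprinted, pluripotency, germline and histone variant lists that differed by 2-fold, and a fixed set of pluripotency, DNA methylation and control genes. Other genes are named only where the text says that their values had been seen.

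The alternatives chosen before the data were examined were the median over a gene's probe sets, probe sets without an s, x or a suffix, no expression filter, a filter at the 75th percentile, median or lowess centring, a 1.5-fold rule, unmatched random lists, and lists without their member of largest difference. The following were chosen after seeing the data: leaving out the 618 and the 1455 values, the 3 sections, the 20-row limit, the limit of 0.4 for the sign of paired probe sets, and the alternatives that keep the repeated control values, leave out both members of each repeated pair, use 1 section alone or match random lists on the section. Leaving out a replicate was not possible.

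The procedure was tested on simulated arrays with 9775 genes past the filter in a knockdown against control comparison. It recovered 100% of the values of a planted step series and 100% of planted repeats. Both were planted in the form that the search looks for, so this recovery was fixed by design. The procedure called 100% of genes planted with log2 differences of 1.5 and 2, and 0 of the others. The simulated noise was normal and far narrower than the 2-fold rule, with a single probe set per gene, so these call rates were fixed by design. They do not measure false calls on the real arrays, where differences past the filter had an SD of 0.34. Of 200 random lists without a planted shift, 5 fell outside the central range. Those were lists of random genes placed among random lists, so the result checks the code and not the real lists. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.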

Results

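Array expression profiles compared mouse ES cells depleted of H2A.B, a short histone H2A variant, with ES cells carrying a control hairpin. The comparison asks which transcripts differ when H2A.B is depleted. Each group had 1 array, so no difference below has a replicate error, and the values describe these 2 arrays. Over usable probe sets the arrays correlated with r = 0.984 across probe sets, which are not independent replicates. Of the 8282 genes past the expression filter, 92.6% differed by less than 0.5 on the log2 scale and the median difference was -0.0016.

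The H2A.B genes H2ab1, H2ab2 and H2ab3 on chromosome X were named by 0 probe sets, so the knockdown itself could not be checked on these arrays. H2al2a, a related H2A gene of chromosome 2 that carries an older H2A.Bbd synonym, had log2 intensities of 3.92 on the control array and 4.03 on the knockdown array, both below the expression filter. Hybridisation spikes had a median difference of 0.0012 over 18 probe sets and the 3 Gapdh control probe sets one of -0.01. Added poly-A spikes were lower on the knockdown array by a median of -0.14 over 24 probe sets, from -0.26 to 0.04. The 3 b-actin control probe sets were higher by a median of 0.36. Gapdh itself differed by -0.02, and Actb had no usable value.

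On the knockdown array 56 genes were at least 2-fold higher. The largest difference was that of Xab2, which encodes an XPA-binding protein of transcription-coupled repair and splicing, with log2 intensities of 6.56 on the control array and 10.85 on the knockdown array (4.28); its 2 probe sets below the filter differed by 0.33 and -0.68. It was followed by the chemokine gene Ccl24 (3.22), the class I histocompatibility gene H2-M10.1 (2.78), the ARF-like GTPase gene Arl16 (2.63), the Y-linked sex-determining gene Sry (2.42) and Nol3 (2.39), an apoptosis repressor. Kidins220, a scaffold of neurotrophin receptors, was 4.03-fold higher and was the brightest of the group. The other genes of the 15 were 4931428F04Rik (2.00), Qpctl (1.99), Rnf217 (1.95), Cdr2l (1.92), Aldh1b1 (1.88), Kcnj16 (1.86), Mobp (1.80) and Itpkc (1.77). Another probe set past the filter existed for 4 of these 15 genes, and all 4 were at least 2-fold higher on it too. The differences were 1.98 for Kidins220, 2.00 for 4931428F04Rik, 2.07 for Cdr2l and 1.96 for Mobp. Over all 4 Kidins220 probe sets they were 2.01, 2.01, 1.98 and 2.00, at control levels from 4.15 to 9.16. What makes these differences so alike at unlike brightness was not tested. Probe sets below the filter existed for 10 of the 15: for 6 genes at least 1 of them was 2-fold higher, as for Arl16 (2.14) and Sry (1.02), and for 4, Xab2, Nol3 (-0.19 and -0.25), Kcnj16 (-0.23) and Itpkc (0.05), none was; Qpctl had -0.05 on one and 2.06 on the other. The count fell to 3 when the filter was set at the 75th percentile of mean intensity, so most of these genes lay at modest intensities.

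On the knockdown array 106 genes were at least 2-fold lower. Zfp101, a zinc finger gene, had 10.80 on the control array and 4.82 on the knockdown array (-5.98). Lmo7, a LIM-domain gene of cell junctions, differed by -5.05, the kainate receptor gene Grik1 by -4.82, the replication initiation gene Ticrr by -4.80 and Kansl1, of the NSL histone acetyltransferase complex, by -4.21. Tom1l2 (-4.20), the homeobox gene Prox1 (-3.80), Gpr158 (-3.79), 4930513N10Rik (-3.59), Sfmbt2 (-3.13), the lysosomal chitobiase gene Ctbs (-3.11), Tenm3 (-3.01), Ppm1l (-2.94), the galactosyltransferase gene B3galt5 (-2.67) and the calcium channel gene Cacna1a (-2.66) made up the rest of the 15. Another probe set past the filter existed for 4 of these 15 genes, and all 4 were within 0.5 on it: -0.15 for Zfp101, 0.04 for Kansl1, 0.30 for Tom1l2 and -0.41 for Ctbs. Probe sets below the filter existed for 14 of the 15: those of Sfmbt2 (-2.82), Tenm3 (-3.02) and Ppm1l (-3.14 and -2.98) were 2-fold lower too, and for the other 11 genes none was. The Kansl1 difference therefore turned to 0.04 when probe sets with an s, x or a suffix were left out. The count fell to 58 with the median over a gene's probe sets and to 17 with the filter at the 75th percentile. The knockdown values of Zfp101, Lmo7 (4.30) and Grik1 (4.39) lay below that array's median of 5.59. So did those of Prox1 (5.08), Tom1l2 (5.17), Tenm3 (5.29), Gpr158 (5.34) and Kansl1 (5.50). Signal over background was not analysed, so the sizes and order of such differences are uncertain.

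**Figure D1:**
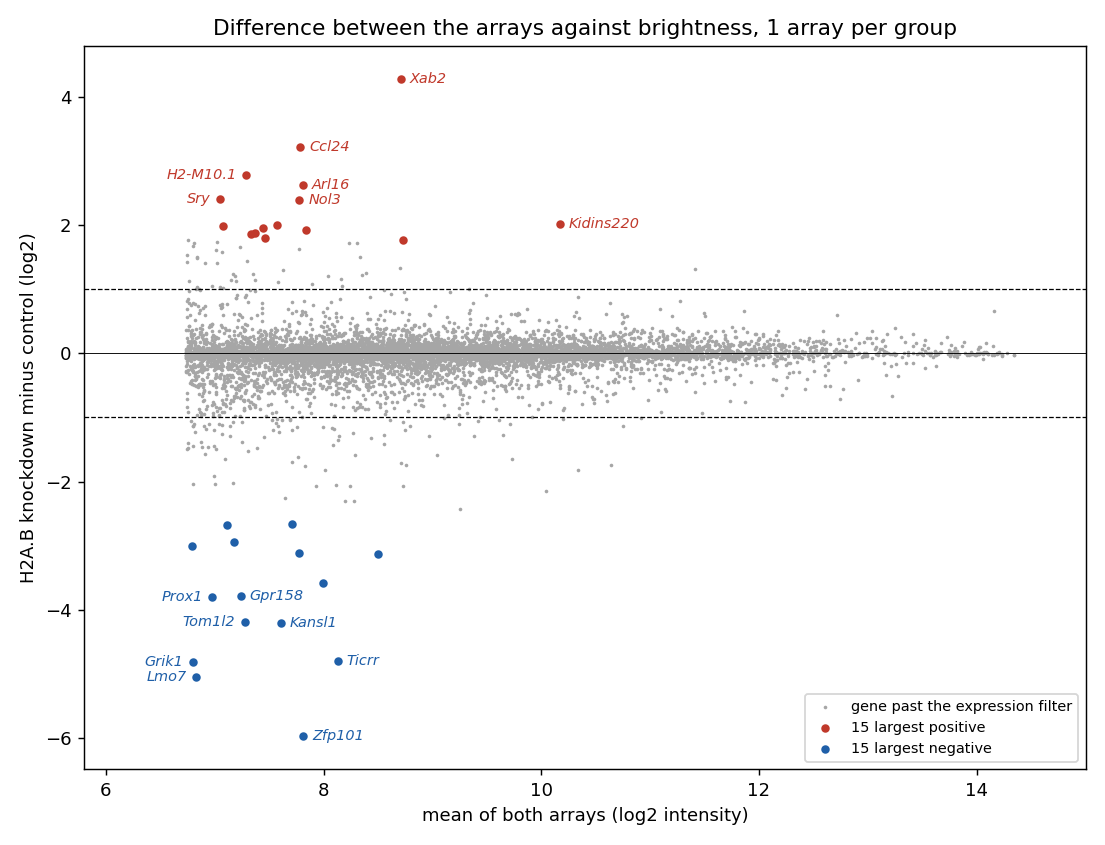
Each point is a gene past the expression filter, with the mean log2 intensity of the 2 arrays on the x axis and the log2 difference, knockdown minus control, on the y axis; red and blue points are the 15 genes with the largest positive and negative differences, and dashed lines mark 2-fold. The points spread from -5.98 for Zfp101 to 4.28 for Xab2, with 56 genes above the upper line and 106 below the lower one.

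Among genes listed as imprinted, that is, expressed from 1 parental allele in at least some tissues, 3 were at least 2-fold lower on the knockdown array. None of them was 2-fold higher. The arrays do not tell the alleles apart, so expression from 1 allele in these cells was not tested. The paternally expressed Sfmbt2, a Polycomb-group gene used in the placenta, was 8.74-fold lower, with 10.07 on the control array and 6.94 on the knockdown array. Its dimmer probe set, below the filter, had 5.29 and 2.47. Igf2, the paternally expressed fetal growth factor gene, was 2.74-fold lower, and Ano1, a maternally expressed chloride channel gene, 2.15-fold lower with -0.95 on its other probe set. Kcnq1ot1, the paternally expressed non-coding RNA of the Kcnq1 domain, was higher by 0.80 and 0.75 on its 2 probe sets past the filter, while its 4 dimmer probe sets differed by -0.50, 0.02, -0.32 and 0.09, and the maternally expressed Cd81 differed by -0.77, Trappc9 by 0.44 and Ascl2 by -0.38; Mcts2 differed by -0.11. As lists, 8 of 10 paternally expressed genes past the filter lay below 0 (median -0.04, percentile 12.4) and 10 of 19 maternally expressed genes did (median -0.03, percentile 15.2), both inside the central range. With the filter at the 75th percentile the maternally expressed list left that range (8 genes, median -0.14, percentile 0.87).

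Pluripotency genes were at nearly the same level on both arrays. Pou5f1, which encodes Oct4, had 12.65 on the control array and 12.64 on the knockdown array, and Sox2 differed by 0.03 and Nanog by -0.09. Of 36 list members past the filter, 0 differed by 2-fold and 35 were within 0.5 (median 0.01, percentile 68.0). The exception was Lefty2, a Nodal antagonist gene, at -0.79 on its single probe set. Tbx3 (-0.37), Esrrb (0.33) and Trim28 (0.30, with 0.11 on its other probe set) followed.

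Germline genes whose promoters are methylated in somatic cells had 16 members past the filter, 8 above and 8 below 0 (median 0.01, percentile 70.1). The RNA-binding protein gene Dazl came closest to 2-fold, at 1.99-fold higher from 6.37 on the control array; its dimmer probe set differed by -0.46. Sycp3 of the synaptonemal complex differed by -0.35, Rhox9 by 0.33 and Piwil2 by 0.26. Histone variants and linker histones had 11 members past the filter, all within 0.5 (median 0.02, percentile 64.1), with H2aw at 0.44, Macroh2a2 at 0.16, H3f3b at 0.04 and H3f3a at 0.04.

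Of the 35 lists with at least 3 members past the filter, 5 lay outside the central range. For lists of randomly drawn genes 1.75 would be expected. The fixed lists share members and are not random draws, so these numbers do not measure an excess over chance. Interferon and viral response genes were lower (12 genes, 9 below 0, median -0.09, percentile 1.06): the interferon-induced Ifi35 differed by -0.55, and the oligoadenylate synthetase family members Oas2 by -0.53, Oasl1 by -0.49 and Oas3 by -0.44. Oxidative phosphorylation genes were slightly lower (38 genes, 24 below 0, median -0.02, percentile 1.89), with the ATP synthase genes Atp5h at -0.42 and Atp5d at -0.31, and the complex I genes Ndufb5 at 0.26 and Ndufv1 at -0.16; Atp5h was at 0.37 and Atp5d at -0.01 on the other probe set of each. Proliferation and mitosis genes were slightly higher (39 genes, 25 above 0, median 0.04, percentile 97.8), with Cdc20 at 0.28, Mcm2 at 0.25, Cenpe at 0.21 and Ccne1 at 0.20. Of the 3 Hox genes past the filter, Hoxa7 differed by 0.79, Hoxa3 by 0.36 and Hoxc9 by -0.02 (median 0.36, percentile 99.7). With no expression filter the 31 measured Hox genes had a median of 0.0032 at percentile 79.2.

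DNA methylation machinery was the remaining list outside the range (22 genes, 15 above 0, median 0.05, percentile 97.53). Zbtb4, which binds methylated DNA, was 2.91-fold higher on its brightest probe set, while its 3 dimmer probe sets differed by -0.07, 0.03 and 0.01. Ehmt1, a histone H3 methyltransferase gene, was 2.03-fold lower on its single probe set, and Gadd45a differed by -0.51. The maintenance methyltransferase gene Dnmt1 differed by 0.11 and its partner Uhrf1 by 0.02, the de novo genes by 0.09 for Dnmt3a and -0.42 for Dnmt3b, Dnmt3l by 0.06 and Tet2 by -0.26. Of these 5 calls, that on DNA methylation ended under 9 of 14 alternatives. Those on oxidative phosphorylation and proliferation each ended under 8 of 14, that on interferon under 4 of 12 and that on Hox under 1 of 7. The Hox count says little, since settings that left fewer than 3 Hox genes were not scored. Those scored mostly recentred the values, rematched the random lists or handled the repeats. The Hox call ended with no expression filter, over 31 genes (percentile 79.2). Oxidative phosphorylation turned to 0.03 in the middle section alone.

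**Figure D2:**
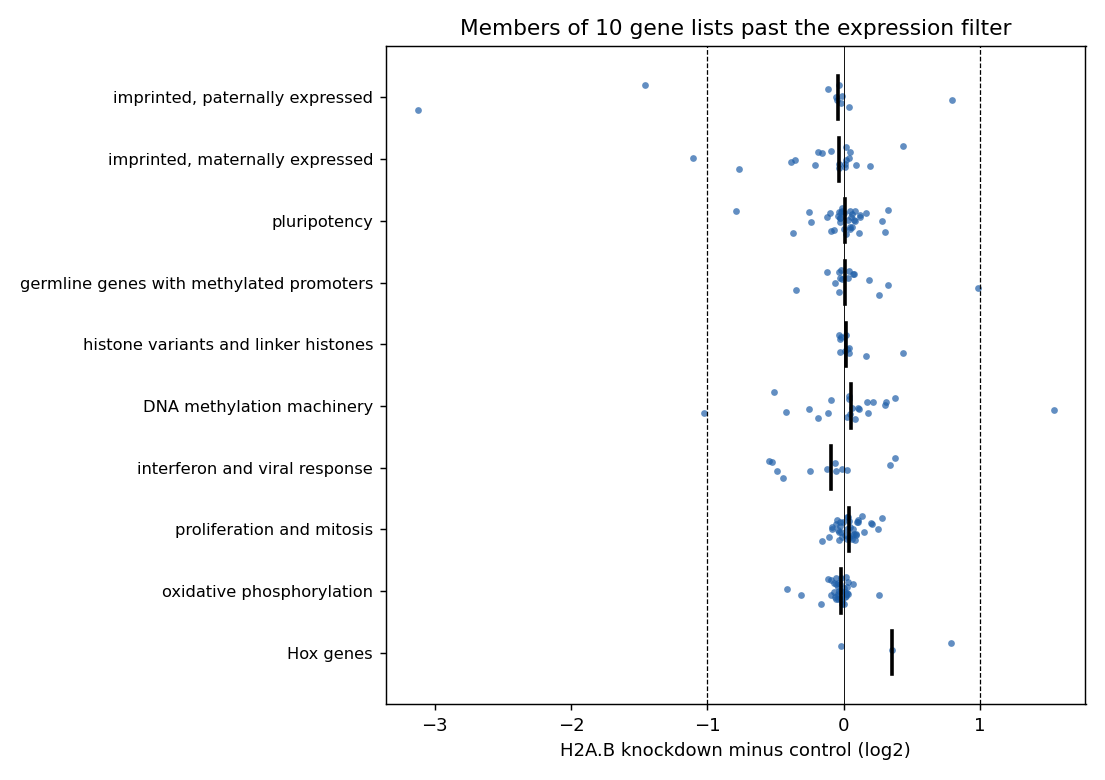
Each point is 1 member past the expression filter of a gene list named on the y axis, placed on the x axis by its log2 difference, knockdown minus control; black bars are list medians, dashed lines mark 2-fold, and vertical scatter within a row has no meaning. Pluripotency genes cluster around 0.01, and Sfmbt2 at -3.13 and Igf2 at -1.46 stand far left of the other paternally expressed genes.

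The other lists of chromatin and transcription genes lay inside the central range. Histone chaperones (20 genes, median 0.03, percentile 89.7) included Spty2d1 at -0.55 and -0.52 on its 2 probe sets past the filter, Hira at -0.39, Anp32e at 0.30 and Nap1l4 at 0.19. Polycomb and Trithorax genes (28 genes, median 0.03, percentile 91.0) included the methyltransferase genes Kmt2b at -0.63 and Kmt2c at -0.53 (0.09 on its other probe set), Eed at -0.33 and Pcgf2 at 0.27. Transcription elongation genes (24 genes, median 0.04, percentile 93.9) included Cdk12 at 0.93 and -0.34 on its 2 probe sets past the filter and Polr2a at 0.36. Splicing factors (38 genes, median 0.02, percentile 79.9) included Sf3b2 at -0.54, with -0.43, 0.29 and -0.49 on its other probe sets. Of 5 replication-dependent core histones, 4 lay below 0 (median -0.09, percentile 12.6), with H2bc22 at -0.40.

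Lineage markers past the filter did not reach 2-fold apart from Igf2, which the placenta list shares. Members below the filter were not assessed singly. They entered only the lists scored with no expression filter, where each of these lineage lists lay inside the central range. Those lists held 21 epiblast (median 0.0046, percentile 67.9), 28 neural (0.0018, 68.8) and 33 mesoderm genes (0.0094, 82.8). The 30 endoderm genes then had a median of -0.0095 at percentile 41.9, and the 25 placenta genes one of -0.0455 at percentile 7.17. The neural gene Elavl4 differed by -0.14 on its probe set past the filter. Its dimmer probe sets differed by -0.68 and -2.99. Primed epiblast genes had a median of -0.01 (11 genes, percentile 43.6), ectoderm and neural genes one of 0.03 (7 genes, percentile 82.2), mesoderm genes one of -0.05 (6 genes, percentile 22.8), endoderm genes one of 0.08 (9 genes, percentile 97.0, and 99.2 among random lists matched on section too) and trophectoderm and placenta genes one of -0.07 (12 genes, percentile 7.42). The largest members were Pax6 (-0.78) of the neural list, Myl7 (-0.80) of the mesoderm list, Dnmt3b (-0.42) of the epiblast list and Krt18 (-0.29) of the endoderm list, which the epiblast and placenta lists share. The dimmer probe sets of Pax6 differed by 0, 0.03 and -0.03. Only 2 genes of the two-cell-like state, Pramel7 (0.05) and Eif1a (-0.02), and 2 spermatid genes, Acrv1 (0.12) and Prm1 (0.03), passed the filter. Fibroblast and feeder markers, which would show carried-over feeder cells, had a median of 0.02 (19 genes, percentile 79.1), with Col6a2 at -0.70, Mmp2 at -0.38, Vim at 0.34 and Col1a1 at 0.25.

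Stress, growth and signalling lists also lay inside the central range. The p53 targets had a median of 0.01 (25 genes, percentile 63.7), with Sesn2 at -0.65 and Ddb2 at 0.51, and senescence and cell-cycle inhibitors one of 0.03 (9 genes, percentile 81.0), with Cdkn2b at 0.38. Heat shock genes had a median of 0.02 (14 genes, percentile 67.2), oxidative stress genes one of 0.03 (21 genes, percentile 89.4) and unfolded protein and amino acid stress genes one of -0.0018 (29 genes, percentile 42.2). The last list left the central range on the other side of 0 with the median over probe sets (0.04, percentile 99.1) and with the filter at the 75th percentile (0.07, percentile 97.8). Ribosomal protein genes had a median of 0.0012 (37 genes, percentile 25.6). Hypoxia and glycolysis genes (27 genes, median 0.0047, percentile 52.3) included the Max interactor gene Mxi1, 2.38-fold lower with -1.06 on its dimmer probe set, and Myc and ribosome biogenesis genes (26 genes, median -0.0026, percentile 38.7) the telomerase gene Tert, 2.61-fold lower on its single probe set. Cholesterol synthesis genes had a median of -0.02 (18 genes, percentile 22.5), with Insig1 at 0.54. Extracellular matrix and adhesion genes had a median of 0.04 (24 genes, percentile 95.3), with Fbln1 at -0.69 and -0.04 on its 2 probe sets past the filter. That list left the range in 3 of 14 alternatives. It was at 98.6 with no expression filter, 99.2 with the filter at the 75th percentile and 97.9 without the member of largest difference. In the other 11 it stayed inside, at percentile 66.8 with probe sets without a suffix and 13.3 (median -0.17) in the last section alone. FGF and MAPK response genes had a median of 0.05 (18 genes, percentile 96.9, and 98.7 among random lists matched on section too). BMP and TGF-beta response genes had one of -0.03 (16 genes, percentile 14.57), with Skil at 0.50. Wnt response genes had one of 0.02 (11 genes, percentile 77.6), with Axin2 at -0.63. Among 13 housekeeping reference genes (median -0.01, inside the central range), the lysosomal glucuronidase gene Gusb was 3.28-fold higher, with 1.92 on its other probe set.

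The differences were not spread alike over the deposited table. Of 4920 genes past the filter in the first section, 3 were higher and 31 lower by 2-fold, against 30 and 46 of 1695 in the middle section and 23 and 29 of 1667 in the last. The median absolute difference was 0.04 in the first section, 0.19 in the middle and 0.19 in the last. Pou5f1, Sox2, Nanog, Dnmt1, Dnmt3l, Uhrf1 and most oxidative phosphorylation and interferon genes were read from the first section, the section with the narrowest distribution. Among others, Xab2, Nol3, 4931428F04Rik, Ticrr, Gpr158, Sfmbt2, Igf2, Lefty2, Tbx3, Esrrb and Gusb were read from the middle section, where control values are repeated and the differences of probe sets of one gene correlated across genes with rho = 0.03 (277 genes; same sign in 23 of the 53 genes where one probe set differed by 0.4 or more). What produced the step series and the repeats was not tested, and the values around them were not re-normalised here from raw array files. The differences of these genes therefore hold only as far as the deposited table does. Some called genes had another probe set past the filter. On such a probe set, 8 of 11 higher genes and 5 of 19 lower genes were at least 2-fold different the same way. In the first section that held for 1 of 1 higher and 0 of 10 lower genes. In the middle section it held for 4 of 6 higher and 5 of 6 lower genes, and in the last for 3 of 4 and 0 of 3.

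**Figure D3:**
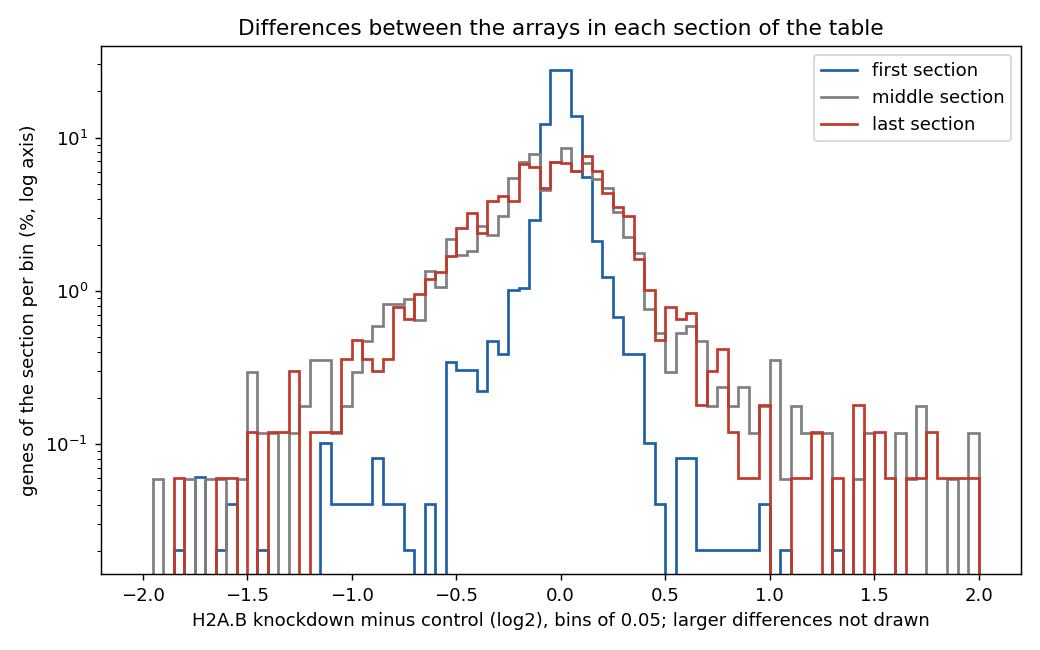
The lines show, for each section of the table, the percent of its genes past the expression filter (y axis, log scale) in bins of the log2 difference, knockdown minus control (x axis). The first section is the narrowest, with a median absolute difference of 0.04 against 0.19 in the middle and last sections, and its left side drops steeply beyond about -0.56.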

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

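Of the tests in this part, those on brightness, on changed values, on the first section's share of lower genes and on chance ties were chosen after the result had been seen; those on steadier genes, on centring and on neighbouring probe sets were written before their results.

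Outside the gene results, 26 probe sets that name no gene were at least 2-fold higher on the knockdown array, of 3144 past the filter, and 41 were at least 2-fold lower. They drew attention because no gene result uses them. Among these probe sets, differences reached 9.57, with 4.06 on the control array and 13.63 on the knockdown array. On the lower side they reached -8.66, with 11.11 and 2.45. Both of these lay in the last section and went beyond the gene results, which ran from -5.98 for Zfp101 to 4.28 for Xab2. Whether such values were altered was not tested. The knockdown column also holds 616 values in a series of steps of 1, at an Actb probe set among others, which are not intensities. The control column holds 1455 values repeated from nearby rows.

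The repeated control values lie in the middle section alone. Where a control value was repeated from the control column, the knockdown values of the same rows differed by at most 0.22 (median 0.05, against 1.56 for random pairs of rows at the same distances). At the 340 values repeated from the knockdown column, every log2 difference was negative, from -0.97 to -0.16. Chance ties of normalised values would be scattered over the table. The section limits were set by clustered repeats, those with at least 5 others within 200 rows. A cluster elsewhere would have moved the limits, but a scattered repeat would have counted as outside them, and 0 were found. Neighbouring probe sets of one gene account for 4.05% of the repeated pairs that both name a gene, 25 of 618. That values in the table were altered after RMA may account for the repeats and for the step series; this was not tested, what produced them stays open, and no biological explanation was tested.

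The array difference was narrower in the first section of the table. Brightness is argued against, since within bins of equal brightness the median absolute difference was still a median of 3.25 times as large in the last section as in the first. That the first section may hold steadier genes stays open, with a ratio of 1.23 among genes with probe sets in both sections, and so do values changed after normalization in part of the table. Where the last-section probe set of a gene differed by 0.4 or more, its first-section probe set had the same sign in 57.6% of 66 genes (Wilson 95% interval 45.6 to 68.8, over genes, which are not replicates), against 34 of 36 between last-section probe sets. Low sign agreement was not particular to the first section, with 36 of 65 genes between the middle and last sections, 23 of 53 within the middle section and 8 of 11 within the first, and no biological explanation was tested.

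More genes were lower than higher on the knockdown array, by a ratio of 1.89. The ratio was 1.84 or more after median and lowess centring, but these moved genes by a median of 0.0016 and 0.0076, too little to test centring, so normalization stays open. The first section may account for part of the excess: it held 31 lower and 3 higher genes, the middle section 46 and 30 and the last 29 and 23. With genes read from 1 section alone, 38 were lower and 9 higher in the first section (ratio 4.22), 51 and 38 in the middle and 35 and 25 in the last (ratio 1.40). An effect of H2A.B depletion on the remaining excess was not testable with 1 array per group.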

How the results depend on the processing

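No paired analysis was possible because each group had 1 array, and leaving out a replicate would leave nothing to compare. The alternatives for 1 section alone, repeated values and section matching were chosen after seeing the data. Of 997 values of named genes under the alternatives, 930 moved by less than the typical spread between probe sets of one gene, 65 moved by more and 2 reversed; of 463 list values, 29 came inside the central range, 12 left it in the direction of the main median, 3 left it on the other side of 0, 1 reversed and the rest kept their side of the range. Of the 930 gene values, 169 each came from median and lowess centring, 168 from keeping the repeated values and 164 from leaving out both members. These settings shift genes little or change few named genes, so the 930 is no measure of stability. With the median over probe sets, 46 gene values moved by more than that spread and 81 by less. Where a value moved and no reason is given, the cause was not tested. Pseudocounts do not apply to log2 values, and the arrays' signal over background was not analysed.

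The 56 higher and 106 lower genes became 187 and 482 with no expression filter, 3 and 17 with the filter at the 75th percentile, and 149 and 318 with the 1.5-fold rule, by the construction of these settings. With the median over probe sets 58 genes were lower, and 46 of the 106 were among them. In the first section alone 9 were higher and 38 lower, in the middle section 51 lower, and in the last section 25 higher and 35 lower; 5253, 2294 and 2459 genes passed the filter in these sections, so the number of genes alone does not give these counts. Median centring kept 56 of the 56 and 105 of the 106 genes, and lowess centring 55 and 106.

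Against 5 lists in the main setting, the number outside the central range was 1 with the median over probe sets, 1 without the member of largest difference, 2 in the middle section alone and 1 in the last alone, with 0 of the 5 among them in each of these 4 settings. It was 2 with probe sets without a suffix and 2 with the repeated control values kept, all among the 5, and 3 with no expression filter, 2 of them among the 5. It was 4 with the filter at the 75th percentile, 1 of them among the 5, and 7 in the first section alone, 3 of them among the 5; the new lists in the first section were endoderm (percentile 99.5), FGF and MAPK (98.8), fibroblast and feeder (98.7) and BMP and TGF-beta (1.55). With random lists matched on section too it was 6, of which 4 were among the 5 and endoderm and FGF and MAPK were new. Extracellular matrix and adhesion genes were the list outside without the member of largest difference. Unfolded protein and amino acid stress genes were the list outside with the median over probe sets (0.0396), and were also outside with the filter at the 75th percentile (0.0658) and in the middle section alone (0.1893). The paternally expressed list had a median of -1.46 over 3 genes in the middle section alone, the maternally expressed list -0.14 with the filter at the 75th percentile, and the germline list 0.33 over 3 genes in the last section alone, each then outside the range. Oxidative phosphorylation reversed to 0.0295 in the middle section alone. Kansl1 reversed to 0.0367 with probe sets without a suffix and to 0.0367 in the last section alone, since both settings take its other probe set.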

Other observations

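The genes, thresholds and ranges in this part were chosen after their values had been seen. For 13 genes, 2 or more probe sets past the filter were each at least 2-fold different in the same direction. By their brightest probe set, 1 of these genes, Kidins220, lay in the first section, and Cdr2l, Mobp and Stk38l lay in the last. The others, Rtel1, Tnpo2, 4931428F04Rik, Gusb, Thra, Ncoa2, Med13l, Parn and Cryz, lay in the middle section, where control values are repeated. Rtel1, the helicase gene of telomere maintenance, was higher on all 4 of its probe sets (mean 1.41, SD 0.16), and Stk38l, a kinase gene, on all 3 (mean 1.26, SD 0.19). Tnpo2, a nuclear import receptor gene, was lower on all 3 (mean -1.04, SD 0.05). Each on 2 probe sets, Kidins220 (mean 1.99), 4931428F04Rik (mean 2.00), Cdr2l (mean 2.00), Mobp (mean 1.88), Gusb (mean 1.82) and the thyroid hormone receptor gene Thra (mean 1.13) were higher, and the nuclear receptor coactivator gene Ncoa2 (mean -1.18), the Mediator gene Med13l (mean -1.18), the poly(A) ribonuclease gene Parn (mean -1.14) and the quinone oxidoreductase gene Cryz (mean -1.04) were lower. The SD is that among probe sets on the same 2 arrays and covers no difference between cultures.

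Probe sets of one gene agreed differently by section, as Spearman correlations across genes, which are not independent replicates. The correlation of their differences was 0.87 over 241 genes within the last section, 0.36 over 1034 genes within the first, 0.03 over 277 genes within the middle section and 0.17 over 784 genes between the first and last sections. In the first section 51 probe sets had a log2 difference from -0.9 to -0.6, against 535 from -0.56 to -0.26; in the last section these counts were 362 and 1148, and in the middle section 368 and 1004.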
